A study of Homo sapiens with 6 samples.

How the data were processed

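RNA of parental and enzalutamide-resistant C4-2b cells grown in serum-containing medium was extracted with Trizol, and libraries were made with the Lexogen QuantSeq kit, which primes at the 3′ end of transcripts, per the labels' protocols. Such a library gives about 1 fragment per transcript whatever its length, so the values were not corrected for length. Per the submitters' processing notes the authors used Bowtie2, edgeR and genome build hg19, with no versions given; the annotation, the read counter and the use of strand are not given in the sources used here. A table of gene symbols with 1 value was deposited for each of the 6 libraries, and every file had 25737 rows, 5952 of them at 0 in all libraries.

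The unit of the deposited values was worked out from the values themselves. The deposited values are on a log2 scale, equal to log2(adjusted count + 1), where the adjusted count is the count moved by quantile adjustment to a common library size with all 6 libraries as 1 group and a single dispersion, fitted as 0.238. Inverting this adjustment gave whole reads. Of 118710 values, 99.992% were matched within 0.001 log2, 8 genes had a value that was not, and 100% of the 56373 values from 1 to 99 reads were whole within 0.1 reads. The library totals and read counts printed are these recovered ones, and a composition factor between 0.953 and 1.146 per library is part of the deposited values. Shallow libraries carry more counting error, and parental replicate 3, with 1614031 reads, is the shallowest against 11162818 in parental replicate 2. Intervals and limits on counts of 0 cover counting error only.

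Symbols listed more than once (286 symbols) were kept once, at the row with the highest mean, which left 24462 symbols and left out 1275 rows. Genes with at least 10 adjusted counts in at least 3 libraries were tested, 12319 in all. The design written before the data were examined named a quasi-likelihood count test. Since the deposited values are log2 values and not counts, the main test became limma 3.58.1 (R 4.3.3) on these values, with a mean-variance trend and robust moderation, Benjamini-Hochberg adjustment and a threshold of 0.05. The 2-fold count used an absolute log2 difference of at least 1 among genes past that threshold. Gene lists, fixed before the data were examined, were tested with limma camera at a preset inter-gene correlation of 0.01 where at least 5 members were tested (26 of 31 lists), with an estimated correlation and fry beside it. Old symbols in the lists were matched through NCBI gene synonyms (assembly GRCh38.p14), which was used for names and for which genes neighbour each other, never for positions.

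The rule for named genes, also fixed before the data were examined, took 10 genes always named, among them KLK3, KLK2, TMPRSS2, FKBP5, NR3C1, AKR1C3, FOLH1 and CHGA; some genes that the rule takes are not reported here. To these it added up to 10 rising and 10 falling genes past the threshold with the largest change, a mean of at least 10 CPM and groups that did not overlap. Symbols starting with LOC, LINC, MIR or SNOR, open reading frame names, XIST and Y-linked genes were left out of this part. For each list it took up to 2 members per direction past the threshold with at least 5 CPM, or else the member with the highest mean CPM. The other genes named, among them list members past the list threshold, were chosen after their values were seen.

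Libraries that share a replicate number deviated from their group means together. The deviations correlated at 0.503, 0.285 and 0.260 across 12319 genes between libraries numbered 1, 2 and 3, above the limit of 0.1 for each pair. Every other pairing was negative, which adds no separate support, since deviations cancel out within each group. The genes vary together, so their number does not measure the strength of the pairing. The labels do not say what the numbers share. The fit without the block was the planned main fit, and the blocked values are given with the gene or list whose calls they change. The 3 called genes have an adjusted p of 0.0334 with the block (limma, Benjamini-Hochberg). No pair of libraries was a duplicate, as the chi-square per degree of freedom of their recovered reads was 16.1 or more for each pair.

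The steps were tested on simulated data for this comparison, with the library sizes, means and spread of the real libraries, over 12045 genes of which 200 were changed. Of 100 genes changed 8-fold 88 were called and of 100 changed 2-fold 3 were called, with 6 of 11845 unchanged genes called. Of 200 lists of unchanged genes, 3 had a camera p under 0.05. The simulated genes were drawn independently of each other, so this could not test camera on lists whose members vary together. The libraries were also drawn independently, with a single spread per gene. Deviations shared by a replicate number, and spread that differs between libraries, were thus left out. The shares of changed genes called may therefore not hold for the real data. In the real data the estimated correlation of the mitosis list was 0.602. Of 32847 simulated values from 1 to 99 reads 99.97% were returned exactly by the inversion.

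The alternatives tried were other scalings, other filters on low values, the replicate block, limma voom on the recovered reads, each library and each replicate number left out, and a test against a fold of 1.5. Added after the data were examined were a pseudocount of 4, library weights, a fit without the variance trend, voom with the block, and the block with an estimated correlation or fry. Counts of list members with each library left out were also added then. Recovery and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.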

Results

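Messenger RNA was profiled in C4-2b, a human prostate cancer cell line derived from LNCaP and metastatic to bone, and in a derivative of it that is resistant to enzalutamide, an antiandrogen drug. Each of the 2 groups held 3 libraries made with a kit that reads the 3′ ends of transcripts, and replicates were numbered 1 to 3 in both groups. The reads in genes, worked back from the deposited values, numbered 5038416, 11162818 and 1614031 in parental replicates 1, 2 and 3, and 5959777, 9215173 and 4196530 in resistant replicates 1, 2 and 3. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The question the comparison addresses is how the transcripts of resistant cells differ from those of the parental line. All differences are resistant minus parental on the deposited scale, log2(adjusted count + 1), which understates the change of genes with few reads. The files list genes by symbol without positions.

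TFPI, PRAC1 and GULP1 were nearly lost from the resistant cells. TFPI encodes an inhibitor of the tissue factor pathway of blood coagulation, PRAC1 a small nuclear protein of prostate and distal colon, and GULP1 an adaptor protein for the engulfment of apoptotic cells. TFPI fell from 7.22 ± 0.50 (SD, n = 3) in parental to 1.36 ± 1.18 (SD, n = 3) in resistant cells, a fold of 57.8. It had 126, 436 and 34 reads in the parental libraries and 0, 8 and 2 in the resistant ones. PRAC1 fell from 8.17 ± 0.40 to 2.58 ± 1.24 (SD, n = 3 each), with 347, 609 and 65 reads against 14, 4 and 4. GULP1 fell from 8.90 ± 0.16 to 3.42 ± 1.39 (SD, n = 3 each), with 439, 868 and 164 reads against 35, 11 and 4. The log2 differences were -5.85 ± 0.67 (SE) for TFPI, -5.59 ± 0.62 for PRAC1 and -5.47 ± 0.63 for GULP1, lower in 3 of 3 replicate pairs, with an adjusted p of 0.0453 each (limma, Benjamini-Hochberg).

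These 3 genes were the whole set past the adjusted threshold of 0.05 among 12319 tested genes in limma, all 3 by more than 2-fold, and no gene rose past it. With library weights, chosen after seeing the data, 40 genes rose and 42 fell. The weights were 4.71 for parental replicate 1 and 2.14 for resistant replicate 3, against 0.354 to 0.789 for the others. Library weights also gave 3109 genes for a split that crosses the groups. Without weights, 738 genes had an unadjusted p under 0.05 in limma. In 1499 genes (12.2%) the 3 libraries of one group lay above the 3 of the other, where chance gives 10%. The count of 3 became 0 without parental replicate 1, 2 or 3 or without resistant replicate 2 or 3, and 0 where the values were scaled by library size only. With limma voom on the recovered reads, 4 genes passed, PRAC1 and GULP1 with SSX2 and SSX2B (the latter pair chosen after their values were seen), while TFPI had an adjusted p of 0.0863 (Benjamini-Hochberg).

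**Figure D1:**
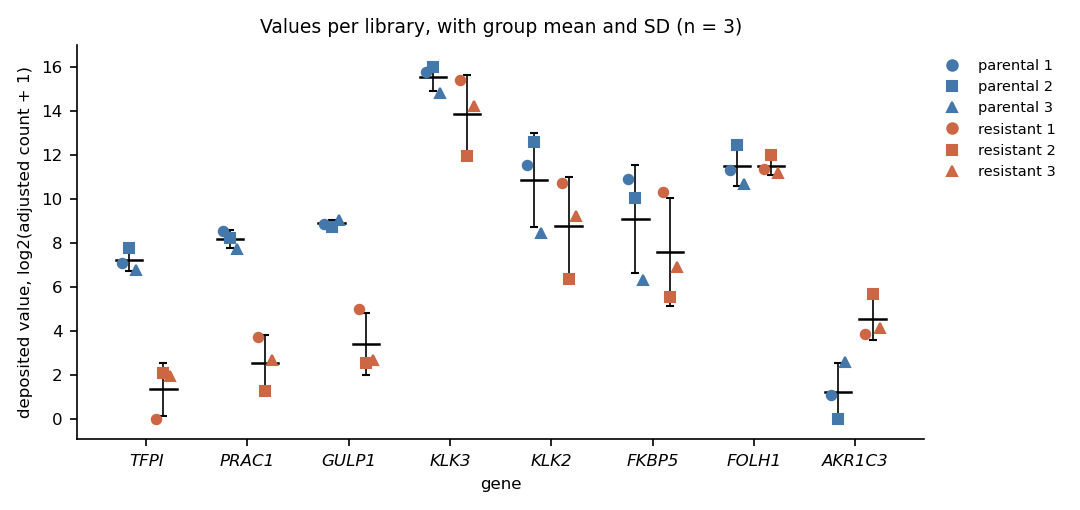
Deposited values, log2(adjusted count + 1), of 8 genes in each library, with replicate number as the symbol, group as the colour, and the mean and SD of each group (n = 3) as bars. TFPI, PRAC1 and GULP1 separate the groups, while FKBP5 ranges from 6.32 to 10.92 within the parental libraries.

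Genes activated by androgen were lower in resistant cells as a list. Of 26 tested members 23 were lower, with a median difference of -0.78, and the list was called lower by limma camera with an adjusted p of 0.00569 (Benjamini-Hochberg over 26 lists, preset correlation of 0.01). With an estimated correlation the adjusted p was 0.843. No member passed, over all genes or adjusted over the list alone. KLK3, the gene of prostate-specific antigen, averaged 15.52 ± 0.63 in parental and 13.86 ± 1.75 in resistant cells (SD, n = 3 each), a difference of -1.66 ± 0.81 (SE), and KLK2, a related kallikrein, differed by -2.08 ± 1.29. FKBP5 differed by -1.50 ± 1.45 and TMPRSS2 by -0.63 ± 0.99, so that these differences were close to or below their errors. The levels of the list overlapped between groups, with mean log2 values of 9.45, 8.96 and 7.28 in parental replicates 1 to 3 and 9.17, 6.58 and 7.41 in resistant replicates 1 to 3. By replicate number the median difference was -0.28, -2.52 and -0.16. It was -0.38 without parental replicate 1 or resistant replicate 2, -1.51 without parental replicate 3 and -1.60 without resistant replicate 1. The camera call ended without parental replicate 1 (adjusted p = 0.256), parental replicate 2 (0.0547), resistant replicate 2 (0.508) or resistant replicate 3 (0.0898). With parental replicate 3 and resistant replicate 1 exchanged between the groups, 21 genes passed over all genes (limma, Benjamini-Hochberg).

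FOLH1, the gene of prostate-specific membrane antigen, differed by 0.03 ± 0.46 (SE), with an adjusted p of 0.997 (limma, Benjamini-Hochberg). It belongs to the androgen-repressed list, of which only 4 members could be tested, 3 of them higher and 1 lower (1 and 3 without resistant replicate 2), and none passed without the replicate block with all libraries. Without parental replicate 3, 1 member rose adjusted over the list alone. With the block CAMK2N1 fell, adjusted over the list alone (difference -0.96, adjusted p = 0.0339, limma, Benjamini-Hochberg).

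Among enzymes of steroid metabolism, AKR1C1 and AKR1C3 were higher in resistant cells. Adjusted over the list alone 2 of 10 tested members rose, AKR1C1 by 4.10 ± 1.10 (SE) and AKR1C3 by 3.33 ± 0.90, both with an adjusted p of 0.0242 (limma, Benjamini-Hochberg), and 0 of 10 rose over all genes (adjusted p of 0.658 each). AKR1C3, which reduces androstenedione to testosterone, had 1, 0 and 1 reads in the parental libraries and 15, 96 and 13 in the resistant ones. AKR1C1 had 0, 3 and 1 reads against 13, 373 and 21. AKR1C2 differed by 2.71 ± 0.95 and did not pass (adjusted p = 0.0672 over the list alone, limma, Benjamini-Hochberg), and AKR1C4, with 0, 0 and 0 reads against 0, 2 and 0, was too low to be tested. These paralogs are close in sequence, so that reads may be divided between them, and their levels are uncertain. The count of 2 became 0 without parental replicate 1 or 2 or resistant replicate 2 or 3, and 3, with 1 further member falling, without resistant replicate 1. The most abundant member, HSD17B4, differed by -0.04 ± 0.36. The list as a whole had a median difference of 0.20 and a camera adjusted p of 0.0536, and was called higher without parental replicate 1 (0.0401) or resistant replicate 2 (0.0426). With an estimated correlation the adjusted p was 0.314. The median by replicate number was -0.02, 0.29 and 0.56. It was 0.41 without parental replicate 1, 0.38 without parental replicate 2, 0.33 without resistant replicate 1, 0.09 without parental replicate 3 and 0.11 without resistant replicate 2 or 3.

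Genes of the cell cycle were lower in resistant cells across both lists. All 26 tested mitosis genes were lower, with a median difference of -1.14, and 15 of them fell adjusted over the list alone, while 0 passed over all genes (limma, Benjamini-Hochberg). Among the 15 were CCNA2, cyclin A, which differed by -1.95 ± 0.42 (SE), AURKA by -1.57 ± 0.39, BIRC5 by -1.34 ± 0.30 and MKI67, the gene of the proliferation antigen, by -1.35 ± 0.42. TOP2A, the most abundant member, differed by -0.94 ± 0.44. All 30 tested DNA replication genes were lower as well, with a median of -0.92, and 10 fell adjusted over the list alone. These included the helicase subunit MCM5, by -1.44 ± 0.30, and the ribonucleotide reductase subunit RRM2, by -2.05 ± 0.44, while RRM1 differed by -0.63 ± 0.34. The camera adjusted p was 3.3e-20 for mitosis and 1.9e-16 for DNA replication, and 0.314 for each with an estimated correlation. With the replicate block 18 mitosis genes fell, TOP2A (adjusted p = 0.0314, against 0.0797 without the block), UBE2C and TTK added, and 12 replication genes, CDC6 and UNG added, adjusted over the list alone (limma, Benjamini-Hochberg). In the fit with no block, the 15 mitosis genes became 6 without parental replicate 1 and 0 without parental replicate 2 or resistant replicate 2. The 10 replication genes became 0 without parental replicate 1, parental replicate 2 or resistant replicate 2, 2 without resistant replicate 3, and 19 without parental replicate 3 or resistant replicate 1.

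**Figure D2:**
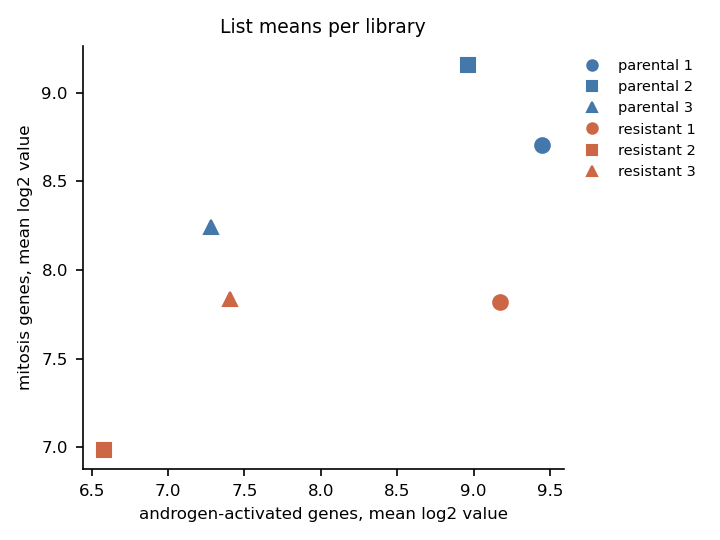
Mean log2 value of the 26 tested androgen-activated genes (horizontal axis) against that of the 26 tested mitosis genes (vertical axis), 1 point per library. The mitosis mean is 8.24 or more in the parental libraries and 7.84 or less in the resistant ones, while the androgen means of the groups overlap.

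Genes of the unfolded protein response and of amino acid stress, tested together as a single list, were higher as a list. Of 20 tested members 17 were higher, with a median difference of 0.93, and 5 rose adjusted over the list alone. They were SLC7A11, the cystine transporter subunit, by 1.44 ± 0.27 (SE), DDIT4 by 2.30 ± 0.58, CHAC1 by 2.48 ± 0.61, TRIB3 by 1.67 ± 0.48 and SESN2 by 1.65 ± 0.46. HSPA5, the abundant chaperone of the endoplasmic reticulum, differed by -0.16 ± 0.34. The list was called higher by camera (adjusted p = 9.0e-09), and the adjusted p was 0.314 with an estimated correlation. With the replicate block 11 members rose and 1, SDF2L1, fell, adjusted over the list alone (limma, Benjamini-Hochberg). Without the block, 0 rose with parental replicate 1 left out, 9 with parental replicate 2 left out and 2 with resistant replicate 2 left out.

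All 16 tested p53 targets were higher, with a median of 0.71 (camera adjusted p = 9.0e-09, and an adjusted p of 0.314 with an estimated correlation). No member rose adjusted over the list alone, against 5 with the replicate block and 9 without parental replicate 3. The median by replicate number was 0.96, 0.93 and 0.07, and it was 0.47 without parental replicate 2, with 14 members higher. GDF15, the most abundant member, differed by 1.36 ± 0.68 (SE). Of 16 tested NRF2 targets, which respond to oxidative stress, 11 were higher, with a median of 0.83 (camera adjusted p = 3.8e-05, and 0.314 with an estimated correlation as the adjusted p). Adjusted over the list alone 2 of these rose, SLC7A11 and AKR1C1, both named above under other lists, and FTH1, the ferritin heavy chain, differed by 1.01 ± 0.81. This count was 0 without parental replicate 1, 1 without parental replicate 2, resistant replicate 2 or resistant replicate 3, and 4 without parental replicate 3 or resistant replicate 1. By replicate number the median was 0.06, 1.45 and 0.24, and it was 0.29 without resistant replicate 2.

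The camera test called 3 further lists higher, with smaller differences. Hypoxia and glycolysis genes had a median of 0.51 with 13 of 19 members higher (adjusted p = 0.00171), immediate early genes 0.41 with 10 of 13 higher (adjusted p = 0.0145), and autophagy and lysosome genes 0.29 with 14 of 16 higher (adjusted p = 0.00569). With an estimated correlation the adjusted p was 0.552, 0.552 and 0.314. No member rose adjusted over the list alone in limma (Benjamini-Hochberg), against 2 hypoxia genes, VEGFA and P4HA1, and 2 immediate early genes, JUND and ATF3 (the latter also in the unfolded protein list), with the replicate block. In the fit with no block, 1 hypoxia gene rose without parental replicate 2 or resistant replicate 1, 1 immediate early gene without parental replicate 1 or resistant replicate 2, and 1 autophagy gene without parental replicate 3. The most abundant members differed little, ENO1 by -0.05 ± 0.38 (SE), IER2 by 0.11 ± 0.37 and CTSD by 0.28 ± 0.53. The hypoxia call ended without parental replicate 1 (adjusted p = 0.116) or resistant replicate 3 (0.177). The immediate early call ended without parental replicate 2 (0.0916), resistant replicate 2 (0.125) or resistant replicate 3 (0.0692), and the autophagy call without parental replicate 2 (0.0916) or resistant replicate 2 (0.0532). Medians within replicates 1 to 3 were 0.42, -0.15 and 0.96 for hypoxia, -0.54, 1.29 and 0.62 for immediate early and 0.39, 0.75 and -0.11 for autophagy genes. The hypoxia median was 0.29 without parental replicate 1 and 0.18 without resistant replicate 3. That of immediate early genes was 0.80 without parental replicate 1, 1.13 without resistant replicate 1 and 0.15 without resistant replicate 2, and that of autophagy genes 0.57 without parental replicate 3 and 0.47 without resistant replicate 1.

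**Figure D3:**
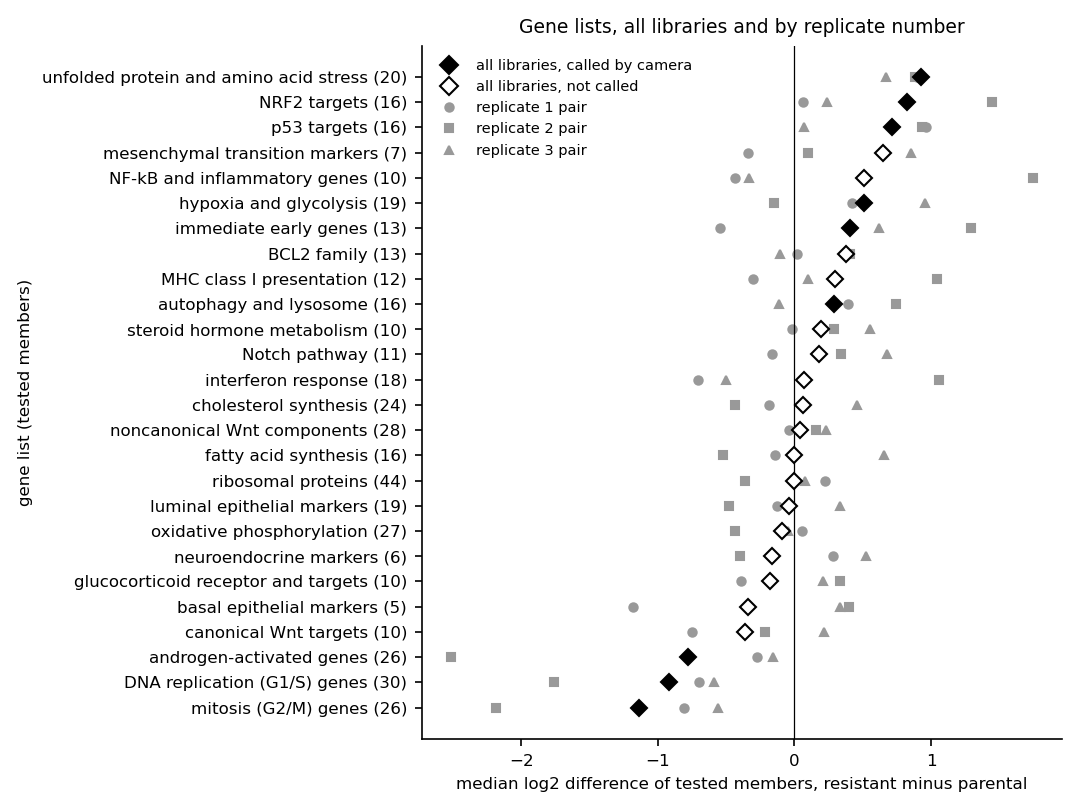
Median log2 difference of each of the 26 tested lists, resistant minus parental, over all libraries (diamonds, filled where camera called the list at an adjusted p under 0.05) and within each replicate number (grey symbols). Among the diamonds, mitosis, DNA replication and androgen-activated genes lie furthest to the left, and the unfolded protein list furthest to the right.

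The lists not called included those of glucocorticoid receptor targets, neuroendocrine, luminal, basal and mesenchymal markers. NR3C1, the glucocorticoid receptor gene, had 0, 1 and 1 reads in the parental and 1, 7 and 1 in the resistant libraries, and CHGA, the neuroendocrine marker chromogranin A, 0, 0 and 0 against 0, 0 and 1. Both were too low to be tested, and for CHGA a count of 0 allows up to 0.595, 0.269 and 1.86 CPM in the parental libraries, counting error only. TSC22D3, a glucocorticoid target, differed by 1.17 ± 0.41 (SE), DLL3 by -0.04 ± 0.33, CDH1 by 0.49 ± 0.40, JAG1 by -0.64 ± 1.05 and FN1 by 0.97 ± 1.05, and none passed. The camera adjusted p was 0.996 for glucocorticoid targets, 0.773 for neuroendocrine, 0.836 for luminal and for basal, and 0.709 for mesenchymal markers. With the replicate block ENO2, a neuroendocrine marker, rose adjusted over the list alone (difference 2.59, adjusted p = 0.00223, limma, Benjamini-Hochberg), against an adjusted p of 0.225 without the block, where 1 neuroendocrine marker rose without resistant replicate 1.

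Among canonical Wnt targets TCF7 fell adjusted over the list alone (difference -3.58 ± 0.83 SE, adjusted p = 0.0184, limma, Benjamini-Hochberg), with 33, 79 and 15 reads in the parental and 0, 8 and 6 in the resistant libraries. This call ended without parental replicate 1, 2 or 3, and the list as a whole had a camera adjusted p of 0.294, with CCND1 at -0.37 ± 0.45 (SE). Noncanonical Wnt components had a camera adjusted p of 0.654, with RAC1 at -0.46 ± 0.27. Metabolic lists were not called, with adjusted p of 0.993 for cholesterol synthesis, 0.836 for fatty acid synthesis (FASN at -0.44 ± 0.88) and 0.773 for oxidative phosphorylation (UQCRB at -0.35 ± 0.34). Nor were lists of immune signalling, with 0.996 for interferon response (ISG15 at 0.11 ± 0.66), 0.619 for MHC class I presentation (B2M at 0.70 ± 0.98) and 0.172 for NF-kB genes (NFKBIA at -0.20 ± 0.38). The BCL2 family had 0.237 (MCL1 at 0.38 ± 0.38), with 1 member rising adjusted over the list alone without parental replicate 3, the Notch pathway 0.490 (HES4 at -0.86 ± 0.44) and ribosomal proteins 0.709 (RPS3 at 0.16 ± 0.49). Of these lists, 5 were called with 1 library left out (limma camera, Benjamini-Hochberg). Without resistant replicate 2, cholesterol synthesis (adjusted p = 0.000325), fatty acid synthesis (0.00158) and ribosomal proteins (0.00195) were called higher. Without parental replicate 2, interferon response (0.00265) and cholesterol synthesis (0.0487) were called lower. NF-kB genes were called higher without parental replicate 3 (0.0480) or resistant replicate 1 (0.00418). In the glucocorticoid, cholesterol, fatty acid, interferon, neuroendocrine and ribosomal lists the sign of the median, of the mean or of the test differed.

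Markers of other cells were few. Of the lists with under 5 tested members, all 4 markers of androgen-independent prostate lines were higher (median 0.84, MSN at 0.23 ± 0.40 SE), and their mean was 7.34 in resistant replicate 3 against 4.96 to 5.27 in the other libraries. Their median by replicate number was 0.15, -0.14 and 2.24. Without resistant replicate 3 it was 0.12, with 3 higher and 1 lower, and without parental replicate 3 also 1 was lower. All 3 fibroblast markers were higher (COL1A1 at 0.24 ± 0.47) and both leukocyte markers lower (CD68 at -0.31 ± 0.82), while no endothelial marker could be tested. Of the fibroblast markers 2 were higher and 1 lower without parental replicate 1, resistant replicate 2 or resistant replicate 3. Both leukocyte markers were higher without parental replicate 1 (median 0.69) or resistant replicate 2 (median 0.80), and their mean was 6.79 and 6.55 in the replicate 1 libraries against 2.43 to 4.76 in the others. None of these passed in limma, over all genes or adjusted over the list alone.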

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

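Tests with library weights, a pseudocount of 4, no variance trend, voom with the block, and the block with an estimated correlation or fry were chosen after seeing the data. The 3 genes, all by at least 2-fold, gave the same count with median-of-ratios and upper-quartile scaling, and 0 with library size only. The count was 6 with no filter beyond 1 read in total, 4 with at least 1 CPM and 4 with voom. Leaving out 1 library gave 0 to 4 genes, and leaving out both libraries of a replicate number 0 to 2. The test against a fold of 1.5 gave 0 genes. Pseudocount 4 gave 4, no variance trend 2 (neither among the 3), voom with the replicate block 6, library weights 82 (40 higher, 42 lower), and weights with the replicate block 263 (120 higher, 143 lower), of which 252 by at least 2-fold. Weights also gave 3109 genes for a split that crosses the groups, and the cause was not tested in any of these cases.

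The 9 lists numbered 6 to 11 with a library or replicate number left out and 9 or 10 under other scalings, filters, weights, voom and pseudocount. The lists called were not always the same. Without resistant replicate 2, 10 were called, 6 of them among the 9, and without both libraries of replicate number 2, 7 were called, 5 of them among the 9. The 9 lists became 0 with an estimated inter-gene correlation, 0 with fry, and 0 for both with the replicate block. The estimated correlation was the only setting of camera that differed from the main test. Without the block its estimates for the 9 lists ran from 0.065 (autophagy) to 0.602 (mitosis), against the preset 0.01. The camera calls thus rest on the preset value, and the cause of the loss with fry was not tested. The replicate block alone gave the same 3 genes and the same 9 lists, and it changed no other call than those of list members given with their lists. One list reversed: without resistant replicate 2, cholesterol synthesis was called higher (adjusted p = 0.000325, limma camera, Benjamini-Hochberg), and without parental replicate 2 it was called lower (0.0487). Its adjusted p ranged from 0.000325 to 0.990 with a library or replicate number left out, against 0.993 in the main test, and the cause was not tested. For single named genes 67 comparisons gained a call and 30 lost one, and for single lists 17 gained and 56 lost one. Changes of sign without a call, 63 for genes and 63 for lists, were not counted as reversed. The planned quasi-likelihood tests, legacy version included, and the planned Wald test were not run; of tests on the recovered reads, limma voom was run. Depth, from 1614031 to 11162818 reads per library, limits genes with few reads.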

Other observations

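The tests of other splits, swapped labels, thinned reads, scaling of the cell cycle lists, the androgen covariate and neighbouring genes were chosen after the results they bear on were seen. Several cancer-testis antigens, normally expressed in germ cells, are given here; they were chosen after their values were seen, and no list of them was tested. CTAG2 had 982, 1286 and 334 reads in the parental libraries and 72, 16 and 1 in the resistant ones, a log2 difference of -6.32 ± 1.04 (SE, adjusted p = 0.307, limma, Benjamini-Hochberg). SSX2 had 33, 68 and 8 reads against 0, 0 and 0, and SSX2B 49, 129 and 16 against 0, 0 and 1, and both passed with voom (adjusted p of 0.0392 and 0.0396) and not in the main limma test (0.105 and 0.0744). CTAG1A had 58, 90 and 41 reads against 6, 9 and 3. SSX2 and SSX2B, and CTAG1A and CTAG1B, are near-identical copies, so that single levels are uncertain. XAGE2 went the other way, with 2, 37 and 1 reads against 37, 121 and 41, and so did XAGE3, with 5, 16 and 5 against 39, 99 and 72 (adjusted p of 0.658 each). In 1499 genes (12.2%, where chance gives 10%) the groups did not overlap. Among them, chosen after their values were seen, were NFIB (-2.32 ± 0.33 SE), the transporter gene SLC22A3 (-2.83 ± 0.42), STC2 (1.92 ± 0.38) and SYT4 (2.13 ± 0.41). None of those named here passed the threshold.

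The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The 3 genes, all by at least 2-fold, were matched or exceeded in 2 of the 10 splits, the real one included, and the highest other split gave 21. The 9 lists were matched in 5 of the 10, with a highest other of 10. The absolute median of each called list was compared over the splits as well, with the real one counted among the 10. A median as large was found in 5 of 10 for androgen-activated genes (highest other 2.29 against 0.78). It was found in 6 for immediate early genes (0.88 against 0.41) and in 3 for autophagy (0.42 against 0.29). For hypoxia (0.78 against 0.51) and DNA replication (1.04 against 0.92) it was found in 2 each. The highest other was below the real value for mitosis (0.92 against 1.14), the unfolded protein list (0.70 against 0.93), NRF2 (0.63 against 0.83) and p53 targets (0.53 against 0.71). The split with 21 genes sets parental replicates 1 and 2 with resistant replicate 1 against the rest, several times the real count, and points to a structure of the samples that the groups do not give. Among the 4 splits that part all 3 replicate pairs, the other three gave 0 genes each, and 10, 10 and 9 lists.

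The mean of the androgen-activated list was high in both replicates 1 (9.45 parental, 9.17 resistant) and low in both replicates 3 (7.28 and 7.41). Replicate 2 differed between the groups (8.96 parental, 6.58 resistant). The low level of parental replicate 3 and the high level of resistant replicate 1 thus went with the replicate number. SLC45A3 had 5161, 7346 and 82 parental reads and 4327, 217 and 250 resistant ones. A swap of the labels of parental replicate 3 and resistant replicate 1 would make the split with 21 genes the true grouping. It would turn every other large difference between them as well. Of 35 genes at least 3 log2 apart between the other 4 libraries, 7 were as far apart the same way between these 2 (CTAG1A, CTAG2, GULP1, PRAC1, SSX2, SSX2B, TFPI), 8 the opposite way and 20 in between, so that a swap accounts for the 8 and not the 7, and it stays open. Depth is argued against, since the range of the list mean over libraries was 2.56 with all reads and 2.54 with every library thinned to the smallest. A state of the cultures that differed between samples of 1 line may account for it and was not tested.

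The lower cell cycle lists, 56 of 56 members, do not come from the scaling, as their median stayed at -1.04 or lower over 4 scalings, nor from depth, as it was -0.93 after thinning. With the level of the androgen-activated list as a covariate the median was -0.79 against -1.12 without it, and 52 of 56 members stayed lower. With 6 libraries this leaves open how much of the difference goes with the androgen list. The androgen and mitosis list means did not go together in every library. They were 9.17 and 7.82 in resistant replicate 1 and 7.28 and 8.24 in parental replicate 3, while both were lowest in resistant replicate 2 (6.58 and 6.98). The androgen level alone thus does not give the order of the mitosis levels. A lower rate of division in the resistant line is a hypothesis that no value here tests.

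TFPI and GULP1 lie next to each other, with 0 protein-coding genes between them in the RefSeq annotation (assembly GRCh38.p14), and both fell. A candidate explanation is a deletion. One that reaches the nearest tested genes on both sides is argued against by their median difference of 0.0315 (ZC3H15 -0.13, ITGAV 0.17, WDR75 -0.11, and COL3A1 0.68 with 22 reads or fewer per library). A smaller deletion, or shared silencing, stays open, as does any biological difference between the lines. Both genes kept some reads in the resistant libraries, which a loss of every copy in every cell would not by itself leave. PRAC1 fell while its neighbours PRAC2 differed by 0.05 ± 0.34 (SE), HOXB13 by -0.88 ± 0.37, HOXB9 by 1.07 ± 0.51 and CALCOCO2 by 0.58 ± 0.37.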
